A study of Mus musculus with 8 samples.

How the data were processed

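The deposited table holds gene-level values headed FPKM, with 1 column for each of the 8 libraries. By its name FPKM is fragments scaled by transcript length and by the mapped fragments of the library. The submitters' processing notes list HISAT2 2.10, Cufflinks 2.2.1, HTSeq and DESeq2 and the builds GRCm38 and mm9, which are different assemblies, with no role or order, and the design text also names other aligners. Which of these made the deposited FPKM table, its annotation and any scaling between libraries are not given in the sources used here. Total FPKM differed between libraries, from 686332 to 1298005, while 10796 to 11197 genes reached 1 FPKM in each.

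Of the 47719 genes listed, 25829 were at 0 in all libraries, 47219 identifiers matched a table of gene names, and 27 symbols that a spreadsheet had turned into dates were restored from their identifiers. Coordinates and transcript lengths were taken from GENCODE release M21 on GRCm38, for 12307 of the genes tested. Read counts and library sizes are unknown. The most common ratio between libraries of FPKM values under 0.1 gave a relative depth scale for each library, with a largest residual of 0.019 in natural log. This scale equals relative fragment numbers only if FPKM was divided by all fragments of a library, which is not known. No interval from absolute counts was computed.

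Libraries were grouped by label as normal control (2), day 2 after hepatectomy (4) and day 14 after hepatectomy (2). The title of day 2 replicate 1 reads day 1 while its age label reads day 2, and it was kept at day 2 and left out in an alternative. The title of day 2 replicate 3 adds the letters TVR, whose meaning is not given. The labels do not state that libraries of a group came from separate mice, so p-values measure the spread between these libraries. FPKM was transformed to log2(FPKM + 1), genes with at least 1 FPKM in at least 2 libraries were kept, and 1 model with 3 group means was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, 5 residual and 3.23 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 3 comparisons. Fixed lists of genes, 39 in all, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the 38 lists of at least 3 measured genes. Beside each list stands the number of members called over all genes and when adjusted over the list alone.

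The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. For each comparison the rule took the 3 most increased and 3 most decreased called genes with non-overlapping groups and a mean of at least 5 FPKM in the higher group, leaving out unnamed gene models. It also took 2 called members of each of 12 lead lists, or where none was called the most abundant member, 1 called member of each other list, and Mki67, Ccnd1, Alb, Cyp7a1, Saa1, Cdkn1a and Afp. Genes with near-identical copies, such as the Saa, Mup, Cyp2c, Sult2a and Hba families, have uncertain levels because shared reads may be divided between copies.

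The alternatives were a pseudocount of 0.1, no filter or a filter at 5 FPKM, median-ratio and quantile scaling, only the 2 compared groups in the fit, limma without the trend, a 2-fold minimum, an estimated correlation and leaving out each library. Removal of the trend with transcript length and GC content in each library, with splines of 4 degrees of freedom, was added after the data had been seen. The method was tested on simulated data with 200 of 12340 genes changed. For day 2 against control it recovered 76% of genes changed by 2 log2 units and 12% of those changed by 1. For day 14 against control these shares were 68% and 0%, and for day 14 against day 2 they were 74% and 6%. Of the genes called in these simulations 7.84%, 4.60% and 8.16% were unchanged. Noise was drawn independently for each gene and library, unlike the day 2 group with its split, so these shares need not hold for the real data. With a simulated trend 1665 unchanged genes were called for day 2 against control, and 14 after the trend was removed. That trend was built from the same 2 properties that the removal fits, so its removal was bound to work and says nothing on other trends. The 2 treatments at day 2 were not compared because no label places a library in either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.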

Results

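RNA from mouse liver was sequenced in 8 libraries: 2 from normal control mice aged 10 weeks, 4 from mice 2 days after an extended hepatectomy, the surgical removal of most of the liver, and 2 from mice 14 days after it. The study concerns human hepatocyte organoids enclosed in a capsule and given to mice with liver failure. Its design text names 2 treatments at day 2, EMC as the treated control and eLO, and eLO alone at day 14. No label ties a day 2 library to a treatment, so the 4 day 2 libraries formed 1 group and the treatments were not compared. By that text day 2 holds both treatments in unknown shares and day 14 only eLO, so time after surgery and treatment cannot be separated in any comparison with day 14. Since the treatments named there cover both hepatectomy groups, surgery and treatment cannot be separated in the comparisons with normal control either. The deposited table gave FPKM, fragments scaled by transcript length and sequencing depth, for 47719 genes, of which 12340 reached 1 FPKM in at least 2 libraries and were tested. Absolute depth was unknown. The most common ratios between libraries of the lowest FPKM values gave depth scales relative to control replicate 1. Such scales need not follow all fragments of a library, since any scaling between libraries is not given. They were 0.99 in control replicate 2, 0.96, 0.85, 1.02 and 1.11 in day 2 replicates 1 to 4, and 0.65 and 0.88 in day 14 replicates 1 and 2. The 2 control libraries correlated at r = 0.988 across genes on the log2 scale and the 2 day 14 libraries at r = 0.963, where genes are not independent replicates. The day 2 group was split, at r = 0.959 between replicates 1 and 2 and r = 0.968 between replicates 3 and 4, and at most 0.926 between these pairs. Replicates 2 and 3 correlated at r = 0.889, below replicate 3 with control replicate 2 at r = 0.904.

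The hepatectomy libraries differed from the controls by transcript length and GC content as well as by gene. For this, 11318 protein-coding genes were divided into 8 equal groups by transcript length. The median level against control in the shortest group exceeded that in the longest by 0.91, 0.92, 0.89 and 0.98 log2 units in day 2 replicates 1 to 4 and by 0.49 and 0.90 in day 14 replicates 1 and 2. The same difference was 0.04 in control replicate 1 and -0.04 in control replicate 2. The group of highest GC content exceeded that of lowest GC content by 0.63 to 1.00 log2 units in the same 6 libraries, the lowest in day 14 replicate 2 and the highest in day 2 replicate 2. Genes called higher at day 2 than in control had a median transcript length of 1516 bases, and genes called lower one of 3340 bases. The comparisons with the controls were therefore repeated after this trend was removed from each library, an alternative chosen after the data had been seen.

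**Figure D1:**
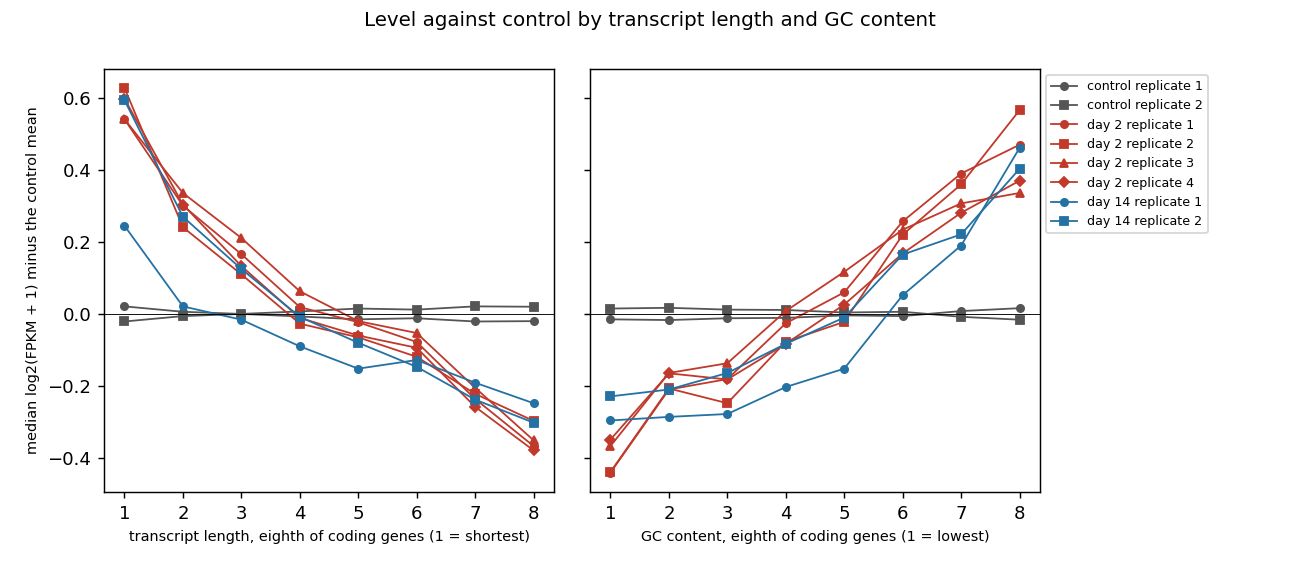
Median of log2(FPKM + 1) minus the control mean (y axis, log2 units) in 8 equal groups of coding genes ordered by transcript length (left) or GC content (right), 1 line per library, grey for control, red for day 2 and blue for day 14. The 2 control lines stay near 0, while all 6 hepatectomy lines fall with length and rise with GC content.

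The comparison of day 2 with normal control asked how the liver remnant early after surgery, by the design text with EMC or eLO, differed from intact liver. Camera called the lists of acute phase genes (12 of 27 rose), oxidative stress and metallothioneins (7 of 17), monocyte markers (6 of 11) and neutrophil markers (3 of 7) higher at day 2. It called those of bile acid genes (13 of 22 fell), xenobiotic cytochromes P450 (9 of 27), urea cycle and amino acid genes (12 of 37) and male-biased genes (14 of 18) lower. All 8 calls were lost when camera estimated the correlation, the lowest adjusted p = 0.0851 with an estimated correlation for male-biased genes and the highest adjusted p = 0.558 with an estimated correlation for neutrophil markers. Lcn2, an iron-binding acute phase protein, averaged 24.8 ± 11.7 FPKM (SD, n = 2) in control and 4288 ± 1991 FPKM (SD, n = 4) at day 2. Its log2 change was 7.31 ± 0.71 (SE) on the log2(FPKM + 1) scale, which understates changes of low genes (limma, Benjamini-Hochberg adjusted p = 0.00174). Car3, a carbonic anhydrase abundant in male liver, averaged 2487 ± 165 FPKM (n = 2) in control and 10.8 ± 14.0 FPKM (n = 4) at day 2. Its log2 change was -8.38 ± 0.82 (limma adjusted p = 0.00174), and -9.08 without day 2 replicate 3. Genes of mitosis were far apart between the 4 day 2 libraries, being high in replicates 3 and 4 and at or under the control level in replicates 1 and 2.

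Of the 27 measured acute phase genes, 12 rose and none fell over all genes tested, and 18 rose and 1 fell when adjusted over the list alone (camera adjusted p = 4.17e-05, adjusted p = 0.516 with an estimated correlation). Saa2 rose by 5.41 ± 0.83 log2 units and its near-identical neighbour Saa1 by 3.86 ± 0.77, to 11235 ± 5233 FPKM at day 2. Reads shared between these copies make each value uncertain. Both lie on chromosome 7 of GRCm38, Saa1 at 46740497 to 46742980 and Saa2 at 46751790 to 46754313. Of 17 genes for oxidative stress and metallothioneins, 7 rose and none fell, with 8 rising when adjusted over the list alone (camera adjusted p = 0.00341, adjusted p = 0.516 with an estimated correlation). Mt2, a metal-binding metallothionein on chromosome 8 of GRCm38 at 94172664 to 94173568, rose by 7.90 ± 0.95 log2 units, and its neighbour Mt1 rose by 7.28 ± 0.83. The controls were far apart, at 5.09 and 91.7 FPKM for Mt2 and 16.1 and 128 for Mt1. Without control replicate 1 the changes were 5.93 and 5.83, and without control replicate 2 they were 9.86 and 8.74. Inflammatory cytokines and NF-kB targets rose in 6 of 17 members, the same number when adjusted over the list alone (camera adjusted p = 0.00775, adjusted p = 0.516 with an estimated correlation), among them the neutrophil chemokine Cxcl1 with a log2 change of 3.95 ± 0.83. Cxcl1 was at 3.15 without control replicate 1 and 4.74 without control replicate 2 and passed in neither. Monocyte and recruited macrophage markers rose in 6 of 11 members, 8 when adjusted over the list alone (camera adjusted p = 0.00379, adjusted p = 0.516 with an estimated correlation), including S100a6 and S100a4, which gained 2.68 ± 0.58 and 2.36 ± 0.46 log2 units. Neutrophil markers rose in 3 of 7 members by either adjustment (camera adjusted p = 0.0095, adjusted p = 0.558 with an estimated correlation). Their median against control was uneven, at 1.8, 4.2, 0.9 and 0.3 log2 units in day 2 replicates 1 to 4. Only 7 of 16 listed neutrophil, 11 of 17 monocyte and 17 of 22 cytokine genes passed the filter of 1 FPKM in 2 libraries. Members low in control could pass through their day 2 levels, which favours a rise at day 2 and a fall from day 2 to day 14. How far this raised the counts was not tested. S100a8, an antimicrobial calprotectin subunit, changed by 3.99 ± 0.86 and Retnlg by 3.76 ± 0.75.

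Bile acid synthesis and transport fell in 13 of 22 members and rose in 1, with 15 falling and 1 rising when adjusted over the list alone (camera adjusted p = 3.5e-05, adjusted p = 0.216 with an estimated correlation). Cyp8b1, the sterol 12-hydroxylase that sets bile acid composition, fell from 190 ± 1.76 FPKM (n = 2) to 1.73 ± 2.21 FPKM (n = 4), and the uptake transporter Slco1a1 fell by 5.13 ± 0.65 log2 units. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, on chromosome 4 of GRCm38 at 6265612 to 6275633, stood at 10.8 and 28.7 FPKM in the controls and at 0.017, 2.42 and 0.74 FPKM in day 2 replicates 2 to 4. It was listed at 0 in day 2 replicate 1 (log2 change -3.57 ± 0.56; limma adjusted p = 0.00642). Xenobiotic cytochromes P450 fell in 9 of 27 members and rose in 1 by either adjustment (camera adjusted p = 0.000221, adjusted p = 0.516 with an estimated correlation). Among them Cyp2f2 changed by -4.15 ± 0.93 and Cyp2c54 by -4.02 ± 0.85 log2 units. Urea cycle and amino acid catabolism fell in 12 of 37 members and rose in 1, with 15 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.00033, adjusted p = 0.516 with an estimated correlation), and included the urea cycle enzyme Otc at -2.95 ± 0.51 and the methyl donor enzyme Bhmt at -2.65 ± 0.63. Lipogenesis fell in 6 of 19 members, 8 when adjusted over the list alone (camera adjusted p = 0.00083, adjusted p = 0.516 with an estimated correlation). The pyruvate kinase gene Pklr changed by -2.57 ± 0.54. Glucose and glycogen metabolism fell in 5 of 19 members, 6 when adjusted over the list alone (camera adjusted p = 0.0209, and 0.052 without day 2 replicate 4, adjusted p = 0.516 with an estimated correlation). G6pc, which releases glucose from its phosphate, changed by -4.62 ± 0.81. Coagulation factors fell in 5 of 18 members by either adjustment (camera adjusted p = 0.00083, adjusted p = 0.516 with an estimated correlation). Hepatocyte transcription factors fell in 5 of 18 and rose in 1, with 8 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.0199, adjusted p = 0.516 with an estimated correlation). Klkb1, prekallikrein, changed by -2.89 ± 0.47 and the transcription factor gene Onecut1 by -2.30 ± 0.52. Onecut1 was at -1.46 without control replicate 1 and -3.14 without control replicate 2, and passed in neither. Cyp7a1 was at -4.24 and -2.91 without control replicates 1 and 2, and did not pass in the latter. Without day 2 replicate 3 Cyp2f2 changed by -4.97 and Cyp2c54 by -4.66. Albumin, Alb, did not pass the test at -0.45 ± 0.42 (limma adjusted p = 0.455). Fatty acid oxidation was not called as a list (camera adjusted p = 0.871, adjusted p = 0.967 with an estimated correlation), but Cyp4a14, a fatty acid hydroxylase induced by PPAR-alpha, rose from 0.457 ± 0.111 to 316 ± 294 FPKM and Acsl1, which activates fatty acids, fell from 213 ± 1.26 to 54.9 ± 19.3 FPKM. The log2 change of Cyp4a14 was 7.11, and 6.49 and 7.93 without day 2 replicates 2 and 3. Over all genes 2 of its 29 members rose and 1 fell, and 1 rose and 1 fell when adjusted over the list alone. Cholesterol synthesis fell in 2 of 25 members, Idi1 and Tm7sf2, and in none when adjusted over the list alone (camera adjusted p = 0.631, adjusted p = 0.948 with an estimated correlation).

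Of the 30 G2/M genes 0 passed limma's test at day 2 by either adjustment and 0 had an unadjusted p under 0.05, although the list was called higher by camera (adjusted p = 0.0182, adjusted p = 0.785 with an estimated correlation). The median of the list against control was -0.52, -0.56, 3.52 and 3.69 log2 units in day 2 replicates 1 to 4. Mki67, a nuclear protein of cycling cells, stood at 0.016, 0.048, 10.5 and 14.9 FPKM in these libraries against 0.35 and 0.51 in the controls (limma adjusted p = 0.399). Ube2c, which marks mitotic proteins for degradation, stood at 1.26, 0.52, 168 and 247 FPKM, and Ccnd1, cyclin D1, at 13.8, 3.36, 48.2 and 51.9 FPKM. The list was not called without replicate 3 (camera adjusted p = 0.366) or without replicate 4 (camera adjusted p = 0.419), nor with a pseudocount of 0.1 (0.157) or a filter at 5 FPKM (0.071). In the list for DNA replication and S phase, 2 members rose and 1 fell of 32 by either adjustment (camera adjusted p = 0.00193, adjusted p = 0.756 with an estimated correlation). The median of this list was 0.23, 0.02, 2.25 and 2.59 log2 units against control in day 2 replicates 1 to 4, so that replicates 1 and 2 lay near the controls. Ccne1, cyclin E1, rose by 2.74 ± 0.41, while Mcm10, a replication factor at 57.3 ± 22.6 FPKM in control, fell by 2.55 on the log2 scale. Among p53 targets 4 of 16 rose by either adjustment (camera adjusted p = 0.03, adjusted p = 0.535 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, on chromosome 17 of GRCm38 at 29090976 to 29100727, rose from 9.20 ± 5.85 to 112 ± 34.8 FPKM (log2 change 3.55 ± 0.39; limma adjusted p = 0.00219), and by 2.93 and 4.17 log2 units without control replicates 1 and 2. The p53 list was not called without day 2 replicate 3 (camera adjusted p = 0.106), day 2 replicate 4 (0.111) or control replicate 1 (0.0646), nor with the filter at 5 FPKM (0.109). Ribosome biogenesis rose in 8 of 22 members, 10 when adjusted over the list alone (camera adjusted p = 0.00193, adjusted p = 0.516 with an estimated correlation). Nhp2 changed by 2.13 ± 0.30. Of 30 growth factors, receptors and early response genes 8 rose and 4 fell by either adjustment, and the list was not called (camera adjusted p = 0.114, adjusted p = 0.516 with an estimated correlation). Its immediate early genes Ier3 and Egr1 rose by 3.84 ± 0.89 and 3.49 ± 0.85, Ier3 by 3.22 without day 2 replicate 2. Extracellular matrix and myofibroblast genes rose in 2 of 19 members, Timp1 at 3.05 ± 0.57 and Col4a2 at 1.19 ± 0.32, and in 1 when adjusted over the list alone (camera adjusted p = 0.00368, adjusted p = 0.558 with an estimated correlation). The fetal liver gene Afp rose from 1.03 ± 0.087 to 16.5 ± 12.4 FPKM (log2 change 2.77 ± 0.68; limma adjusted p = 0.0262). It was the 1 riser among 3 measured of 13 listed fetal liver genes, whose median was -0.09 log2 units. That list was not called (camera adjusted p = 0.66, adjusted p = 0.794 with an estimated correlation).

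**Figure D2:**
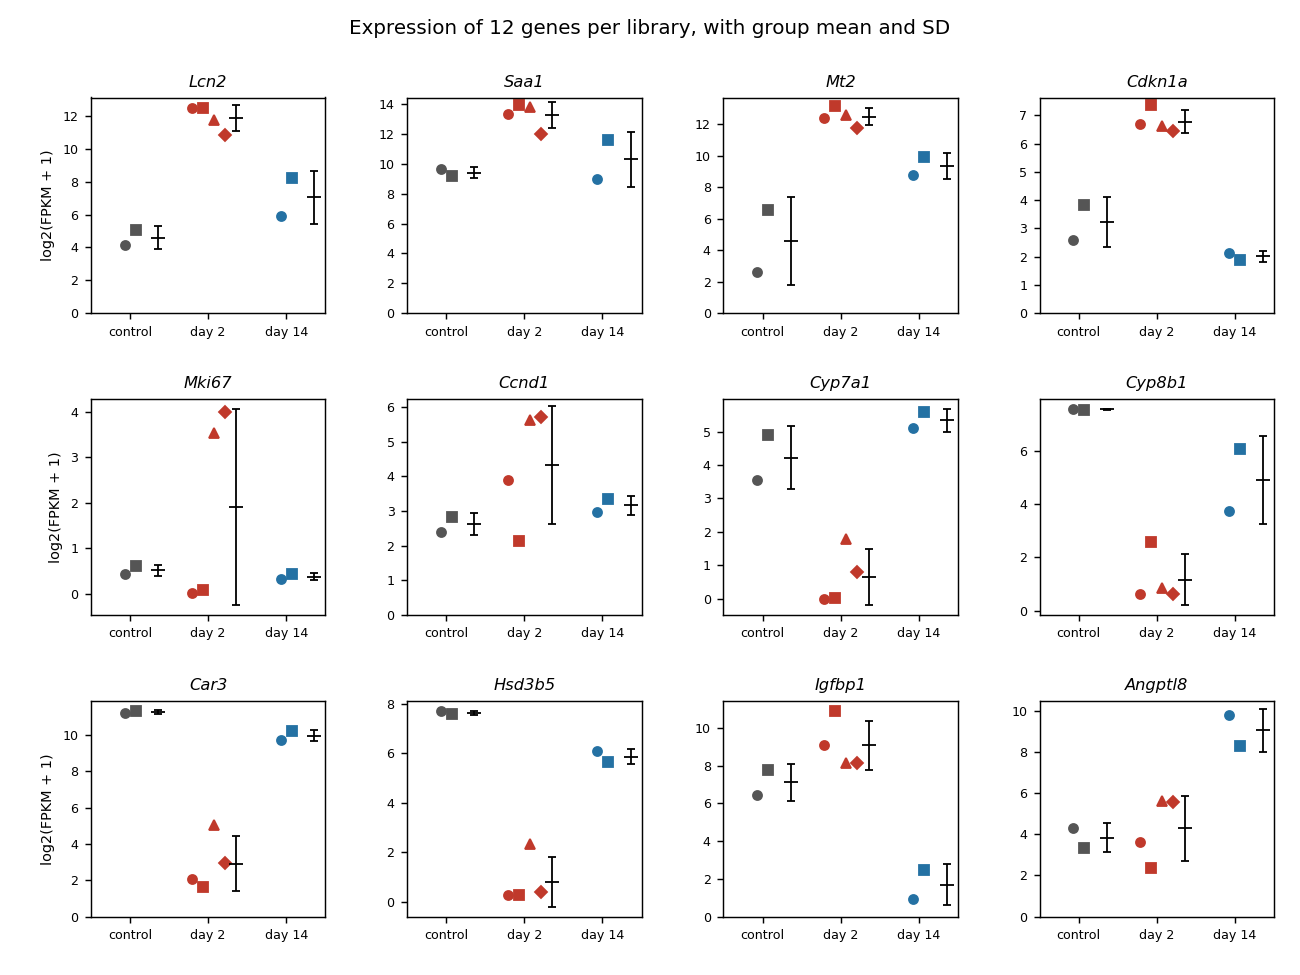
log2(FPKM + 1) of 12 genes (y axes) in each library, grouped as control (grey), day 2 (red) and day 14 (blue), with circles, squares, triangles and diamonds for replicates 1 to 4 and a black bar for the group mean and SD. Lcn2 and Cdkn1a are higher in all 4 day 2 libraries than in either control, Cyp8b1 and Car3 are lower, and Mki67 is high in day 2 replicates 3 and 4 only.

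Over all 12340 genes, 2620 changed between day 2 and control at an adjusted p under 0.05, 1200 higher and 1420 lower (limma on log2(FPKM + 1), Benjamini-Hochberg). After the length and GC trend was removed 1690 genes were called, 645 higher and 1045 lower, of which 1411 were calls of the same direction in both fits. Of the 48 named genes called, 43 kept their call. Of those that lost it, Idi1 went from -2.62 to -2.23 ± 0.63 log2 units, Col4a2 from 1.19 to 1.03 ± 0.34 and Fabp4 from 2.30 to 2.33 ± 0.67, at limma adjusted p of 0.051, 0.0807 and 0.0541. Ndufa2 went from 1.32 to 0.77 ± 0.32 and Uty from -1.07 to -0.42 ± 0.22. With no filter on low values Afp, Col4a2, Egr1, Fabp4, Ndufa2 and Tm7sf2 lost theirs, and Col4a2 and Fabp4 also with only the 2 compared groups in the fit. All 18 lists called by camera kept their call after the trend was removed, with fewer members called in several. Members called higher went from 12 to 11 for acute phase, 8 to 4 for ribosome biogenesis, 7 to 5 for oxidative stress, 6 to 4 for inflammatory cytokines, 6 to 3 for monocyte markers and 2 to 1 for matrix genes. The list median went from 1.12 to 0.73 log2 units for oxidative stress and from 1.14 to 0.72 for monocyte markers. Members called lower went from 13 to 12 for bile acid genes, 12 to 11 for the urea cycle list and 14 to 13 for male-biased genes, and from 9 to 10 for cytochromes P450 and 5 to 6 for coagulation factors. With control replicate 1 left out 96 genes were called and with control replicate 2 left out 92. Without each of the 8 libraries in turn, 9 of the 48 named genes, Lcn2, Mt1, Mt2, Car3, Hsd3b5, Sult2a8, Cyp8b1, Cdkn1a and Marco, kept their call.

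The comparison of day 14 with normal control asked how liver 14 days after surgery, by the design text with eLO, differed from intact liver. The hepatocyte lists called lower at day 2 were not called at day 14. Their medians against control at day 14 were -0.72 log2 units for lipogenesis, -0.67 for coagulation factors and -0.53 for bile acid genes. They lay between -0.25 and 0.23 for the other such lists. For coagulation factors camera's adjusted p was 0.0868, and 0.983 with an estimated correlation. Simulations recovered 0% of single genes changed by 1 log2 unit here, so few called members do not show a return to control. No changed list was simulated for day 14, so the lack of list calls does not show one either. For day 2 against control a simulated list raised by 1 log2 unit was called (camera adjusted p = 2.67e-24). Its genes varied independently, unlike those of a real list. Camera called mitochondrially encoded genes higher (0 of 9 past limma's test, 9 at an unadjusted p under 0.05) and endothelial (4 of 20 fell) and Kupffer cell markers (3 of 14) lower. Each of these calls was lost at camera's adjusted p = 0.983 with an estimated correlation. Angptl8, a secreted regulator of lipoprotein lipase induced by feeding, averaged 14.2 ± 7.10 FPKM (SD, n = 2) in control and 608 ± 407 FPKM (n = 2) at day 14. Its log2 change was 5.23 ± 1.08 (limma adjusted p = 0.0328). Igfbp1, an insulin-repressed binding protein of insulin-like growth factors on chromosome 11 of GRCm38 at 7197782 to 7202546, averaged 154 ± 96.5 FPKM in control and 2.69 ± 2.55 FPKM at day 14, and changed by -5.43 ± 0.96 (limma adjusted p = 0.0263). Angptl8 was at 4.48 and 5.97 without day 14 replicates 1 and 2 and passed in neither. Igfbp1 was at -6.11 and -4.74 without control replicates 1 and 2 and at -4.66 without day 14 replicate 1, and did not pass in these 3 fits, and changed by -6.20 without day 14 replicate 2.

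The 9 measured mitochondrially encoded genes were higher as a list at day 14 (camera adjusted p = 0.000753, adjusted p = 0.983 with an estimated correlation), with 0 past limma's test over all genes, 9 at an unadjusted p under 0.05, and 9 higher when adjusted over the list alone. Mitochondrial mRNA made up 40.7% of all FPKM in day 14 replicate 1 and 16.0% in replicate 2, against 7.95% and 7.56% in the controls and 11.1%, 20.4%, 6.95% and 11.3% in day 2 replicates 1 to 4. Sinusoidal and other endothelial markers fell in 4 of 20 members, 8 when adjusted over the list alone (camera adjusted p = 0.00504, adjusted p = 0.983 with an estimated correlation). The hyaluronan receptor gene Lyve1 changed by -1.98 ± 0.35. Kupffer cell markers fell in 3 of 14 members, 6 when adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.983 with an estimated correlation). Adgre1, which encodes a macrophage surface antigen, changed by -1.83 ± 0.38, and the call was lost without day 14 replicate 2 (camera adjusted p = 0.0581). Erythroid and megakaryocyte markers rose in 2 of 10 members, 4 when adjusted over the list alone (camera adjusted p = 0.0122, adjusted p = 0.983 with an estimated correlation). The alpha globin copy Hba-a2 changed by 3.35 ± 0.83. Ribosome biogenesis rose in 3 of 22 members and fell in 1, with 7 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.0143, adjusted p = 0.983 with an estimated correlation), and Nop56 gained 2.63 ± 0.35 log2 units. With the filter at 5 FPKM the ribosome biogenesis (camera adjusted p = 0.0802), endothelial (0.103) and Kupffer (0.103) lists were not called.

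Single members changed in lists that were not called. The acute phase genes Orm2 and Saa3 rose by 3.41 ± 0.79 and 3.16 ± 0.67 log2 units, 2 of 27 by either adjustment, and Saa1 did not pass at 0.88 ± 0.89 (limma adjusted p = 0.554). Of 22 bile acid genes 0 passed limma's test, with 1 higher and 5 lower at an unadjusted p under 0.05. Of 27 xenobiotic cytochromes P450 0 passed and 2 had an unadjusted p under 0.05. Cyp7a1 stood at 33.2 and 46.7 FPKM (limma adjusted p = 0.285). In the urea cycle and amino acid list 3 of 37 fell by either adjustment, including Cbs at -1.84 ± 0.32 and Gldc at -1.60 ± 0.38. In fatty acid oxidation Etfdh changed by -1.94 ± 0.37 and Hadha by -1.34 ± 0.32, 2 of 29 by either adjustment. Idi1 was the 1 of 25 cholesterol synthesis genes that fell, by 3.57 on the log2 scale, and Gpam, the first enzyme of glycerolipid synthesis, was the 1 of 19 lipogenesis genes that fell, by 2.04 on that scale, and 0 did when adjusted over the list alone. Idi1 was at -2.79 without day 14 replicate 1, where it did not pass, and at -4.34 without day 14 replicate 2. The nuclear receptor gene Nr1i3 rose by 2.06 ± 0.41 and the apolipoprotein gene Apoc1 by 1.64 ± 0.35. Atf5, a stress-response transcription factor, changed by -1.84 ± 0.26, and the mitochondrial respiratory gene Sdha by -1.72 ± 0.41. The metallothionein Mt2 was still higher at 4.76 ± 1.09 log2 units, and Bax, a p53 target, at 1.39 ± 0.29. The change of Mt2 was 2.80 without control replicate 1 and 6.73 without control replicate 2, and that of Orm2 was 4.58 and 2.24 without day 14 replicates 1 and 2, and neither passed then. Among the largest decreases were Rnf125, a ubiquitin ligase gene, at -5.15 ± 0.56 and Ece1, endothelin-converting enzyme, at -4.67 ± 0.76. Both were also under the control mean at day 2, at 3.23 ± 2.74 FPKM against 76.5 ± 11.2 for Rnf125 and 87.7 ± 84.7 FPKM against 770 ± 252 for Ece1. Snora57, a small nucleolar RNA, was at 66.8 and 46.0 FPKM at day 14 and listed at 0 in the other 6 libraries. Of the 30 G2/M and 32 S phase genes 0 passed limma's test and 0 had an unadjusted p under 0.05, and Mki67 stood at 0.24 and 0.35 FPKM. The spread behind this test took in the split day 2 group, with SEs of 1.32 log2 units for Mki67 and 2.39 for Ube2c. Such genes could hardly pass, so the 0 calls do not decide on a change. The G2/M median against control was -0.18 and -0.14 log2 units in day 14 replicates 1 and 2, and the S phase median 0.16 in both.

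Between day 14 and control 1208 genes changed, 643 higher and 565 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 464 were called after the length and GC trend was removed, 216 higher and 248 lower. Of 29 genes named by the fixed rule, 12 kept their call after that removal, among them Igfbp1, Rnf125, Ece1, Saa3, Cbs, Idi1, Atf5, Nop56 and Adgre1. Of those that lost it, Apoc1 went from 1.64 to 0.78 ± 0.31 log2 units and Bax from 1.39 to 0.71 ± 0.33. The others named above kept a larger share of their log2 change and ended at a limma adjusted p of 0.0518 to 0.0875. Angptl8 went from 5.23 to 4.49 ± 1.15, Orm2 from 3.41 to 3.13 ± 0.73, Hba-a2 from 3.35 to 2.54 ± 0.75 and Nr1i3 from 2.06 to 1.83 ± 0.43, and Mt2 ended at a limma adjusted p of 0.0708. Lyve1 went from -1.98 to -1.73 ± 0.39, Gldc from -1.60 to -1.55 ± 0.37, Etfdh from -1.94 to -1.75 ± 0.40, Hadha from -1.34 to -1.16 ± 0.31, Gpam from -2.04 to -1.87 ± 0.47 and Sdha from -1.72 to -1.51 ± 0.37. With no filter on low values Angptl8, Mt2, Orm2, Saa3, Apoc1, Hba-a2, Gldc, Gpam, Hadha, Sdha, Lyz2, Nfkbiz and Arntl lost theirs. All 5 lists kept their call after the trend was removed, and 2 with the filter at 5 FPKM. After the removal 0 of 20 endothelial markers passed limma's test, with 9 lower and 1 higher at an unadjusted p under 0.05, and 0 of 10 erythroid markers, with 5 higher. Members called went from 3 higher and 1 lower to 2 higher for ribosome biogenesis, from 2 to 1 for acute phase genes and from 3 to 1 for the urea cycle list. For fatty acid oxidation they went from 2 to 0, with 4 lower at an unadjusted p under 0.05, and for lipogenesis from 1 to 0, with 4 lower and 1 higher. Without day 14 replicate 1, the library with 40.7% mitochondrial mRNA, limma called 0 genes, with 2099 at an unadjusted p under 0.05. It called 662 without day 14 replicate 2, 1 without either control, 521 without day 2 replicate 1 and 2097 without day 2 replicate 2.

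The comparison of day 14 with day 2 asked how the 2 times after surgery differed, and the controls enter it only through the spread of the model. Camera called bile acid genes (11 of 22 rose), xenobiotic cytochromes P450 (6 of 27), lipogenesis (5 of 19) and male-biased genes (11 of 18) higher at day 14. It called acute phase genes (10 of 27 fell), matrix genes (5 of 19) and monocyte and macrophage markers (4 of 11) lower. These calls were lost when camera estimated the correlation, the lowest adjusted p = 0.101 with an estimated correlation for male-biased genes and the highest adjusted p = 0.618 with an estimated correlation for lipogenesis. Cyp7a1 rose by 4.68 ± 0.56 log2 units (limma adjusted p = 0.00405), and Car3 rose from 10.8 ± 14.0 FPKM (n = 4) to 1014 ± 221 FPKM (n = 2), a log2 change of 7.07 ± 0.82 (limma adjusted p = 0.00393). Cdkn1a fell from 112 ± 34.8 to 3.03 ± 0.51 FPKM (log2 change -4.77 ± 0.39; limma adjusted p = 0.00143), and Igfbp1 fell from 765 ± 793 to 2.69 ± 2.55 FPKM (log2 change -7.40 ± 0.83; limma adjusted p = 0.0038). Without day 2 replicate 3 Car3 changed by 7.77. Igfbp1 was at -6.79 without day 2 replicate 2, -8.17 without day 14 replicate 2 and -6.63 without day 14 replicate 1, where it did not pass.

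Bile acid synthesis and transport rose in 11 of 22 members and fell in 1, with 13 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.00134, adjusted p = 0.537 with an estimated correlation), and Cyp8b1 gained 3.74 ± 0.73 log2 units. Xenobiotic cytochromes P450 rose in 6 of 27 members, with 10 rising and 1 falling when adjusted over the list alone (camera adjusted p = 0.000757, adjusted p = 0.552 with an estimated correlation). Cyp2c54 changed by 3.98 ± 0.85 and Cyp2a5 by 3.74 ± 0.89. Hepatocyte transcription factors rose in 8 of 18 members, 9 when adjusted over the list alone (camera adjusted p = 0.00168, adjusted p = 0.537 with an estimated correlation). Nr1h4, the bile acid receptor FXR, changed by 2.60 ± 0.44. Urea cycle and amino acid catabolism rose in 6 of 37 members, with 8 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.03, adjusted p = 0.618 with an estimated correlation). Otc changed by 3.24 ± 0.51 and Prodh by 2.91 ± 0.43. Lipogenesis rose in 5 of 19 members, 6 when adjusted over the list alone (camera adjusted p = 0.0214, adjusted p = 0.618 with an estimated correlation). Thrsp, a lipogenic regulator, changed by 4.99 ± 1.00. Secreted hepatocyte proteins rose in 9 of 27 members and fell in 1, with 10 rising and 2 falling when adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.618 with an estimated correlation). Serpina6, which binds corticosteroids, changed by 4.96 ± 1.38. Fatty acid oxidation and ketogenesis was lower as a list (camera adjusted p = 0.0453, adjusted p = 0.618 with an estimated correlation), with 3 of 29 falling and 1 rising, and 6 falling and 1 rising when adjusted over the list alone. After the length and GC trend was removed the list median went from -0.67 to -0.60 log2 units and the call was lost (camera adjusted p = 0.0936). Its members Cyp4a14 and Acsl1 moved apart, at -6.15 ± 0.97 and 2.16 ± 0.34. Without day 14 replicate 2 the calls of urea cycle (camera adjusted p = 0.403), lipogenesis (0.0513) and secreted proteins (0.123) were lost. Without day 2 replicate 4 those of urea cycle (0.069), lipogenesis (0.069) and fatty acid oxidation (0.0767) were lost, the last also without day 2 replicate 2 (0.16) or day 14 replicate 1 (0.29). The fatty acid oxidation list was also not called with a pseudocount of 0.1 (camera adjusted p = 0.054) or the filter at 5 FPKM (0.0829), nor were secreted proteins with quantile scaling (0.14). Cyp8b1 was at 4.90 without day 14 replicate 1 and 2.57 without day 14 replicate 2, and passed in neither. Without day 2 replicate 3 Cyp2c54 changed by 4.62, Thrsp by 5.84, Serpina6 by 6.08 and Cyp4a14 by -6.97, and without day 2 replicate 2 Cyp4a14 changed by -5.53. Serpina6 was at 4.24 and 4.29 without day 2 replicates 1 and 2 and passed in neither.

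Acute phase genes fell in 10 of 27 members and rose in 1, with 15 falling and 1 rising when adjusted over the list alone (camera adjusted p = 4.89e-05, adjusted p = 0.552 with an estimated correlation). Lcn2 changed by -4.87 ± 0.71 and Saa2 by -4.24 ± 0.83. Extracellular matrix and myofibroblast genes fell in 5 of 19 members, 9 when adjusted over the list alone (camera adjusted p = 7.01e-05, adjusted p = 0.54 with an estimated correlation). Timp1 changed by -2.78 ± 0.57 and the basement membrane collagen gene Col4a1 by -2.27 ± 0.37. Monocyte and recruited macrophage markers fell in 4 of 11 members, 6 when adjusted over the list alone (camera adjusted p = 0.000897, adjusted p = 0.537 with an estimated correlation). Plac8 changed by -1.78 ± 0.32. Genes for oxidative stress and metallothioneins fell in 6 of 17 and rose in 1, with 8 falling and 2 rising when adjusted over the list alone (camera adjusted p = 0.0243, adjusted p = 0.552 with an estimated correlation). The glutathione transferase gene Gsta1 changed by -2.60 ± 0.49. Growth factors, receptors and early response genes fell in 7 of 30 members and rose in 3, with 12 falling and 5 rising when adjusted over the list alone (camera adjusted p = 0.03, adjusted p = 0.537 with an estimated correlation). Ier3 changed by -3.57 ± 0.89. Among p53 targets 4 of 16 fell by either adjustment (camera adjusted p = 0.0145, adjusted p = 0.552 with an estimated correlation). In the unfolded protein and integrated stress response 2 of 24 fell and 1 rose by either adjustment (camera adjusted p = 0.00707, adjusted p = 0.552 with an estimated correlation). The serine synthesis gene Psat1 changed by -2.77 ± 0.32. The G2/M list was lower (camera adjusted p = 0.00569, adjusted p = 0.618 with an estimated correlation) with 0 of its 30 members past limma's test and 0 at an unadjusted p under 0.05. The call was lost without day 2 replicate 3 (camera adjusted p = 0.169), day 2 replicate 4 (0.209) or day 14 replicate 2 (0.0506). Without day 14 replicate 2 the calls of growth factors (camera adjusted p = 0.122), oxidative stress (0.0672) and p53 targets (0.0753) were lost, the last also without day 2 replicate 4 (0.069). These 3 lists were also not called with the filter at 5 FPKM (camera adjusted p = 0.134, 0.0704 and 0.0763). Lcn2 was at -3.70 and Saa2 at -2.92 without day 14 replicate 1, where neither passed, and without day 14 replicate 2 they changed by -6.03 and -5.57. Afp fell by 3.08 on the log2 scale and Mcm10 rose by 3.20 ± 0.51. Serpina4-ps1 rose by 7.71 ± 0.84, and Ly6d, a surface protein gene, changed by -6.44 ± 0.73. They were at 6.98 and -5.63 without day 14 replicate 1, where neither passed, and without day 14 replicate 2 they changed by 8.44 and -7.25. Without day 2 replicate 3 Serpina4-ps1 changed by 8.31, and without day 2 replicate 2 Ier3 changed by -2.95.

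The S phase list was lower at day 14 than at day 2, with 1 of 32 members rising and 1 falling by either adjustment (camera adjusted p = 0.00707, adjusted p = 0.618 with an estimated correlation). That call was lost without day 14 replicate 2 (camera adjusted p = 0.0602), day 2 replicate 3 (0.0507) or day 2 replicate 4 (0.0711). Mitochondrially encoded genes were higher, with 1 of 9 rising and 0 when adjusted over the list alone (camera adjusted p = 0.00707, adjusted p = 0.618 with an estimated correlation), and the call was lost without day 14 replicate 1 (camera adjusted p = 0.21). Kupffer cell markers fell in 2 of 14 members and rose in 1, with 6 falling and 1 rising when adjusted over the list alone (camera adjusted p = 0.0286, adjusted p = 0.552 with an estimated correlation). Without day 14 replicate 2 (camera adjusted p = 0.0799) or day 2 replicate 4 (0.069) the Kupffer list was not called. Endothelial markers fell in 3 of 20 members by either adjustment (camera adjusted p = 0.0486, adjusted p = 0.618 with an estimated correlation). After the length and GC trend was removed the endothelial median went from -0.46 to -0.39 log2 units and the call was lost (camera adjusted p = 0.0808). It was also lost without day 14 replicate 1 (0.208), day 14 replicate 2 (0.0506), day 2 replicate 1 (0.0713) or day 2 replicate 4 (0.202). With median-ratio scaling its camera adjusted p was 0.0537, and the filter at 5 FPKM ended the endothelial (0.727), Kupffer (0.101) and erythroid (0.0627) calls. Erythroid and megakaryocyte markers rose in 1 of 10 members by either adjustment (camera adjusted p = 0.0304, adjusted p = 0.552 with an estimated correlation), a call lost without day 14 replicate 1 (camera adjusted p = 0.0709) or day 2 replicate 3 (0.0937).

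**Figure D3:**
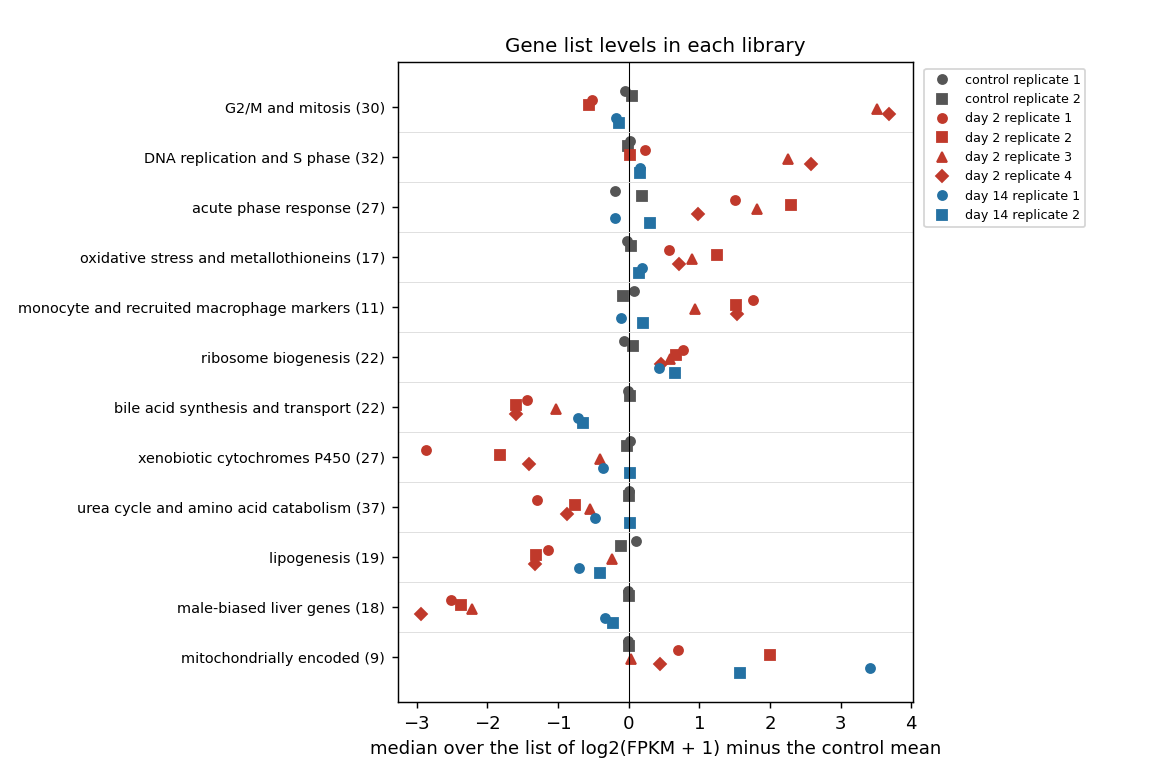
Median over each fixed gene list of log2(FPKM + 1) minus the control mean (x axis, log2 units) in each library, with the number of measured genes in parentheses, grey for control, red for day 2 and blue for day 14. The G2/M list lies at -0.52, -0.56, 3.52 and 3.69 in the 4 day 2 libraries, while male-biased genes lie at or under -2.21 in all 4.

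Between day 14 and day 2, 1990 genes changed, 1122 higher and 868 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 2073 were called after the length and GC trend was removed. The count was 17 without day 14 replicate 1, 1246 without day 14 replicate 2, 1249 without day 2 replicate 1, 984 and 987 without control replicates 1 and 2, and 996 with only the 2 compared groups in the fit. In that fit Ccne1, Cyp2a5, Dcn, Ier3, Kdm5d, Lgals3, mt-Nd2, Mvk, Ndufs1, Oasl1, Saa1, Serpina6 and Vcam1 lost their call, and all of these but Mvk, Ndufs1 and Vcam1 also lost it with no filter on low values. Cdkn1a was the 1 of 47 named genes that kept its call without each library in turn. Of the 24 lists called, 8 kept their call without each library in turn. The lists of T and NK cells and of B cells could not be tested without either day 14 library, and 13 lists were called without day 14 replicate 2.

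Of the genes called against control at both times, 256 were higher at both and 330 lower at both, against 62.5 and 65.0 for independent lists of the same sizes among 12340 genes. In 100 simulations of unchanged groups sharing 2 controls, the mean number called in the same direction was 0.01 and the highest 1, which follows from their few calls and gives no bound on what shared controls add to real changes. The covariance of the log2 changes was 0.395 against a simulated 0.092. Their correlation across genes was lower than simulated, at r = 0.497 against 0.579, and so was the share of genes with the same sign, at 68.6% against 69.6%. After the length and GC trend was removed, 69 genes were higher at both and 135 lower at both, against 11.3 and 21 for independent lists. With control replicate 1 for day 2 and control replicate 2 for day 14 the covariance was 0.355, and 0.382 the other way round, an alternative chosen after the data had been seen. Calls were not made with split controls, which leave 1 library for each comparison, so part of the excess of shared calls may come from the shared controls. The count in the same direction was 0 without either control or without day 14 replicate 1, where limma called 1, 1 and 0 genes at day 14. It was 237 without day 2 replicate 1, 900 without day 2 replicate 2, 377 without day 2 replicate 4 and 251 without day 14 replicate 2.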

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

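All tests of explanations in this part were chosen only after the result was seen. Day 2 libraries were screened for 1 library far from the other 3, and 9 of 143 genes, lists and library measures stood out, where chance gives about 1 in 20, or 7.15. Hsd3b5 was highest in replicate 3, with a gap of 0.942 of the whole range of log2(FPKM + 1). Cyp8b1 was highest in replicate 2, with a gap of 0.876 of the range. Klkb1 was lowest in replicate 1 (gap 0.844), as was Dbp (gap 0.963). Timp1 (gap 0.857), Lyve1 (gap 0.845) and the list of Y-linked genes used to check the sex of the mice (gap 0.925) were lowest in replicate 3. Atf5 was lowest in replicate 4 (gap 0.906), and mt-Nd2 was highest in replicate 2 (gap 0.850).

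Effects against control differed between the times for 10 genes called in opposite directions, where a difference between day 14 and day 2 follows from that selection, and for 6 genes after the length and GC trend was removed. Serpina4-ps1 changed by -3.80 log2 units at day 2 and by 3.91 at day 14, a difference of 7.71 (limma adjusted p = 0.0036). Nrep changed by -2.62 and 2.46, a difference of 5.08 (limma adjusted p = 0.000158).

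G2/M genes lay far apart between the 4 day 2 libraries, the largest gap between neighbouring medians in rank order being 4.04 log2 units. The depth scales of these libraries lay near each other, with a log2 range of 0.385. FPKM is already divided by depth, so this range is not the shift that depth would cause and cannot be set against the gap. Noise in low genes would move members both up and down. In replicates 3 and 4 the median of the 30 genes stood at 3.52 and 3.69 log2 units against control. This argues against such noise for the high levels of these replicates. For the low medians of replicates 1 and 2 an effect of depth through noise was not tested. An earlier harvest may account for replicate 1, whose title reads day 1 and whose median was -0.52 against control, and this stays open because title and age label differ. The same stays open for replicate 2, with a median of -0.56 and a title that reads day 2, since a title is not a measurement. The treatment also stays open, since 0 of the 4 libraries carry a label that names it, and the letters TVR in the title of replicate 3 alone are not explained by any label.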

How the results depend on the processing

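Removal of the length and GC trend and all alternatives of the overlap were chosen after the data had been seen. No paired analysis was made because the replicate numbers of the hepatectomy groups only follow the order of deposition. The numbers in the titles were not used, although day 2 replicate 1 and day 14 replicate 1 both carry a 2. After the length and GC trend was removed, 1690 genes changed at day 2 and 464 at day 14 against control, and 204 were shared. With only the 2 compared groups in the fit, 3239 genes changed at day 14 against control and 996 at day 14 against day 2. In these fits 967 genes were shared, with fewer libraries behind the spread. In the main fit the 3 groups shared 1 spread, so the split between day 2 libraries entered the p-values of day 14 against control. That fit called 1208 genes at day 14 against control, 2097 without day 2 replicate 2 and 521 without day 2 replicate 1. For day 14 against control 8 lists were called with no filter, 2 with the filter at 5 FPKM and 9 with only 2 groups, and for day 14 against day 2 15 were called with the filter at 5 FPKM. With an estimated correlation camera called 0, 0 and 0 lists. Without each library in turn, called genes ranged from 92 to 2971 for day 2 against control, 0 to 2097 for day 14 against control and 17 to 2472 for day 14 against day 2, lists from 16 to 19, 5 to 7 and 13 to 26, and shared genes from 0 to 900. A group left with 1 library was assumed to vary like the others. Signs turned for named genes that were not called. Alb between day 14 and day 2 was -0.46 with quantile scaling and -0.064 to 0.41 without each library. Against control at day 14, without each library Cyp2e1 ranged from -1.59 to 0.39, Saa1 from -0.43 to 2.19 and Afp from -0.74 to 0.13, and Mki67 was 0.24 with the trend removed. Where no construction is named, the cause was not tested. Under the alternatives fixed beforehand, leaving out libraries aside, 42 of 48, 16 of 29 and 34 of 47 called genes named by the fixed rule kept their calls in the 3 comparisons. By the depth scales, low genes were limited most in day 14 replicate 1, at 0.65 of control replicate 1. That library also had the largest share of mitochondrial mRNA, at 40.7% of FPKM.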

Other observations

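All tests of explanations in this part were chosen only after the result was seen. Male-biased liver genes fell together at day 2. Of 18 measured, 14 fell against control and 16 when adjusted over the list alone (camera adjusted p = 1.07e-09, adjusted p = 0.0851 with an estimated correlation), with medians of -2.51, -2.37, -2.21 and -2.94 log2 units in replicates 1 to 4. Hsd3b5, a steroid dehydrogenase of male liver, fell by 6.82 on the log2 scale and Elovl3, a fatty acid elongase, by 5.06. Between day 2 and day 14 11 of the 18 rose, 15 when adjusted over the list alone (camera adjusted p = 5.74e-09, adjusted p = 0.101 with an estimated correlation). Elovl3 was the 1 member called lower than control at day 14, with 3 lower at an unadjusted p under 0.05 and a list median of -0.17, and changed by -4.07 ± 0.72 (limma adjusted p = 0.0263), and was at -3.36 without day 14 replicate 1, where it did not pass, and -4.78 without day 14 replicate 2. Of 4 Y-linked genes used to check the sex of the mice, Uty and Kdm5d fell at day 2 by either adjustment, with a list median of -0.73, and the list was not called (camera adjusted p = 0.0614). After the length and GC trend was removed the median was -0.18, and 0 of the 4 passed limma's test or had an unadjusted p under 0.05. Between day 2 and day 14 1 of the 4 rose, 2 when adjusted over the list alone (camera adjusted p = 0.0298, adjusted p = 0.537 with an estimated correlation). That call was lost without day 14 replicate 1 (camera adjusted p = 0.0752) or day 2 replicate 3 (0.0577), and after the length and GC trend was removed (0.167), as the median went from 0.80 to 0.47. Of 8 female-biased genes 3 rose at day 2, among them Sult1e1, an estrogen sulfotransferase, from 0.215 ± 0.041 to 42.0 ± 31.3 FPKM, and the list was not called (camera adjusted p = 0.156). These 8 were all that passed the filter of 18 listed, and members low in control could pass through their day 2 levels.

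Few lymphocyte markers passed the filter of 1 FPKM in 2 libraries, 3 of 18 for T and NK cells and 3 of 12 for B cells. Without either day 14 library both lists fell under 3 measured genes. The filter thus took members through their day 14 levels, which favoured a rise at day 14 beforehand, and the tests below cannot decide on one. The measured members were low and higher at day 14 than at day 2. Of 3 T and NK cell markers 2 rose, 3 when adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.537 with an estimated correlation), and Gzmb, granzyme B, stood at 5.48 and 1.70 FPKM at day 14 and was listed at 0 in day 2 replicates 1 and 3. Of 3 B cell markers 2 rose, 3 when adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.537 with an estimated correlation), with Ighm, the immunoglobulin M heavy chain, at 1.66 ± 0.31. Alas2, the erythroid enzyme of heme synthesis, fell by 2.19 on the log2 scale from control to day 2 and rose by 3.10 ± 0.29 to day 14. Kupffer cell markers moved apart at day 2, where Marco, a scavenger receptor, rose by 3.96 ± 0.36 while 3 of 14 fell. Noncoding classes stood higher at day 14 than in control, with medians of 0.51 log2 units over 170 lincRNAs and 0.53 over 240 antisense genes against -0.04 over 11318 coding genes, values that were not tested, and reads of antisense genes and their partners cannot be separated without strand.

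Clock genes differed from control at both times. At day 2 the list was not called (camera adjusted p = 0.919), with 2 of 16 members higher and 3 lower, and 4 and 4 when adjusted over the list alone. Ciart was already higher then, by 2.65 ± 0.42 log2 units (limma adjusted p = 0.00667). At day 14 clock genes differed from control in opposite directions, in a list that was not called (camera adjusted p = 0.356). Members other than Ciart were chosen after their values were seen. Ciart, Per2, Per3, Dbp and Tef rose, by 4.56 ± 0.48, 3.29 ± 0.45, 2.72 ± 0.36, 3.50 ± 0.56 and 1.60 ± 0.34, and Arntl and Clock changed by -2.02 ± 0.48 and -1.24 ± 0.24, while Npas2 was at 1.68 and 1.26 FPKM in control and listed at 0 at day 14. All 5 risen members kept their call after the length and GC trend was removed, which argues against that trend for them, and the 3 fallen ones lost it as Arntl went to -1.81 ± 0.52 and Clock to -0.89 ± 0.24, their median with Npas2, no bound with Npas2 at 0, moved from -1.30 to -1.16 and limma's adjusted p rose to between 0.0628 and 0.0822. A harvest at another time of day may account for the 8 called members, and it stays open because 0 labels give a time. All 8 follow their arm of the clock, but the arms were written down after these values were seen, so this cannot decide. The other 8 of the 16 members were not called, and none of them had an unadjusted p under 0.05. Without day 14 replicate 1 (limma adjusted p of Ciart 0.16), control replicate 1 (0.146) or control replicate 2 (0.136) 0 of the calls still tested remained, and Clock, Tef, Npas2 and Arntl lost theirs without day 14 replicate 2 (0.0699, 0.0581, 0.087 and 0.106) and Npas2 and Arntl without day 2 replicate 1 (0.0547 and 0.0589).

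Log2 changes against control followed transcript length in all 6 hepatectomy libraries. Among transcripts of middle GC content, those of 3000 to 4000 bases exceeded those of 6000 bases or more by 0.35 log2 units at day 2 (95% interval 0.22 to 0.46). A correction for fragment length acts on short transcripts, so this argues against it as the whole cause at day 2. Its part among shorter transcripts was not tested. At day 14 the same difference was 0.13 (95% interval 0.024 to 0.25), too close to the margin of 0.1 to tell. Both intervals come from resampling genes and do not measure the spread between libraries. Control libraries made or handled apart from the others may account for the trend, and 0 labels name a batch. Hepatectomy itself stays open too, with a difference between shortest and longest genes of 0.90 in day 14 replicate 2 and 0.49 in replicate 1, and these 2 explanations cannot be told apart, since every hepatectomy library is compared with the same 2 controls.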
